A study of Mus musculus with 2 samples.

How the data were processed

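RNA-seq of polyadenylated RNA was made from 2 libraries of mouse bone marrow-derived macrophages, each from 1 µg of RNA with a size range of 250 to 400, per the labels. Both libraries belong to the only group, so there was no comparison between conditions, and replicate numbers were taken from the labels. Reads were quantified against the mouse genome mm10 with GENCODE annotation M21, per the deposited notes, and the aligner and quantification tools and their versions are not given in the sources used here. The authors deposited 3 tables per library. The alignment-derived gene and transcript tables hold expected counts and TPM made from an alignment to the transcriptome, per the deposited notes and file headers. The FASTQ-derived transcript table holds estimated counts and TPM made from 4 FASTQ files and an index, per the deposited notes and file headers. Whether the counting used strand is not given in the sources used here, so antisense and overlapping genes cannot be told apart with certainty.

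The alignment-derived gene table was the main table, and expected counts were rounded to whole numbers for count-based steps. Both libraries had 55536 gene entries, and all of them matched the annotation, which supplied gene types and coordinates. A further 26248 entries with numeric names held 0 counts and 97 entries were spike-in targets. Among these the bacteriophage phiX174 took 0.0526% of counts in replicate 1 (exact interval 0.0520 to 0.0533%) and 0.0667% in replicate 2 (0.0658 to 0.0676%), and it stayed out of library sizes. Total counts of 41938439 and 30780685 set the precision, so that a count of 0 allows up to 3 counts, or 0.0715 and 0.0975 CPM. Sequencing reads are not independent molecules, so intervals and floors cover counting error only.

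A gene was called detected at a TPM of at least 1 in both libraries. Scaling used TMM factors from edgeR 4.0.16 in R 4.3.3, with DESeq2 1.42.0 size factors and total counts as alternatives. The ratio between the libraries was always replicate 2 over replicate 1, on TMM-scaled counts with 0.5 added, and its interval was an exact (Clopper-Pearson) binomial interval at 95%. For list ratios a gene needed a mean of at least 20 counts over both libraries, and for the 2-fold rule at least 20 counts in each. The common dispersion came from edgeR with an intercept-only design. No gene was tested between the libraries, since there is 1 on each side, and a 2-fold rule was used instead. A chi-square of the counts served only to check for a library deposited more than once. List levels were set against 10000 random lists of protein-coding genes, and list ratios and isoform shares against 10000 lists matched on expression among 200 neighbours. The lists of primary and secondary genes were compared with a two-sided permutation test of 100000 resamples. For isoforms, transcripts annotated as retained intron or processed transcript were summed for genes at 10 TPM or more. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

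The 26 gene lists, the rule for named genes, and the tests and alternatives of the main results were fixed before the data were examined. The tests of technical explanations, and the alternatives that removed shared or low list members, were added later. Named genes were the 10 most abundant protein-coding genes, the 3 highest members and the lowest member of each list, 24 genes of inflammation and Tlr4 signalling whatever their value, the 5 highest and 5 lowest ratios between replicates at 100 or more mean counts, and the 5 largest differences between quantifications at 10 TPM or more. Other list members named as examples of a group were chosen after their values were seen. The lists covered macrophage identity, immediate-early, primary and secondary inflammatory genes, interferon-stimulated genes, negative regulators, Tlr4 pathway components, NF-kB and IkB genes, Toll-like receptors, alternative activation, cell cycle, glycolysis, cholesterol synthesis, MHC classes I and II, heat shock, mitochondrially encoded and sex-linked genes, and markers of T cells, B cells, neutrophils, dendritic cells, NK cells, mast cells, erythroid cells and stroma. The symbol Aldoa had more than 1 entry, and the entry with the higher TPM was used.

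The steps that score genes and lists were tested on simulated data. In counts simulated from the libraries over 12517 genes, with 200 genes changed 4-fold, the 2-fold rule recovered 100% of those made higher in replicate 2 and 98% of those made lower, and 0.317% of unchanged genes passed it. These counts had a dispersion of 0.02, below the 0.0274 estimated from the libraries, and only genes with at least 200 summed counts were changed. The 0.317% is therefore not a rate for the real libraries. A simulated dispersion of 0.02 was estimated as 0.0198 over 13561 genes and one of 0.1 as 0.0973 over 13416 genes. Of 200 random lists of 20 genes without a shift, 6.50% fell outside the central 95% of matched lists. Genes were simulated independently of each other, so this share need not hold for lists whose genes vary together. Alternatives were another TPM minimum or pseudocount, other scaling, other count filters, the FASTQ-derived tables summed per gene, and each replicate left out.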

Results

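The study measured polyadenylated RNA in mouse bone marrow-derived macrophages, which are phagocytes grown in culture from marrow precursors of the C57BL/6J strain. The cells were given Lipid A at 100 ng/mL for 12 h, kept without it for 12 h, and given Lipid A again at 100 ng/mL for 30 min. Lipid A is the part of bacterial lipopolysaccharide that the receptor Tlr4 recognises. The free-text label names Lipid A, whereas the treatment label of the same samples names lipoprotein A, and the labels do not resolve this. There was 1 group of 2 biological replicates and no untreated or singly treated library was analysed here, so every value describes the restimulated state and none describes induction. The labels give the replicates separate biosamples under a shared donor record and do not say whether they came from separate animals. Counts assigned to genes came to 41938439 in replicate 1 and 30780685 in replicate 2. Values are given as mean ± SD over both libraries (n = 2), or for each library. Intervals on ratios and shares are exact 95% intervals that cover counting error only.

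Fth1 (ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098, mm10) and Ftl1, the heavy and light chains of ferritin, stood at 47776 ± 3497 and 18550 ± 1297 TPM (SD, n = 2). Saa3, an acute-phase protein, reached 18112 ± 3389 TPM and the chemokine Ccl5 15495 ± 2260 TPM. B2m, the light chain of MHC class I, Psap, Tmsb4x, Lyz2 and Ctsd followed, between 13733 ± 1040 TPM for B2m and 9693 ± 504 TPM for Ctsd, a lysosomal protease. The other member of the leading 10 genes was mt-Atp8, at 23493 ± 5065 TPM, whose value differed between the deposited quantifications. This short gene (7766 to 7969 of the mitochondrial genome) held 7871 and 6307 counts, whereas mt-Co1 held 250433 and 236458 counts at 7913 ± 1270 TPM. The rank of mt-Atp8 therefore rests on TPM alone and is uncertain. The 10 most abundant protein-coding genes of each library took 18.0 ± 0.737% of TPM, against 13.4% in the FASTQ-derived table and 11.4% of expected counts, each with its own leading 10. A TPM of at least 1 in both libraries was met by 10727 of 22028 protein-coding genes, 133 lincRNA genes and 130 antisense genes, and 1224 protein-coding genes reached 100 TPM in both.

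Genes of macrophage identity were all expressed. Each of the 20 listed members was detected, 17 of them at 100 TPM or more in both libraries, and the list median was 1357 TPM in replicate 1 and 1234 TPM in replicate 2. Lyz2, lysozyme of myeloid cells, stood at 10038 ± 2278 TPM, Adgre1, which encodes the F4/80 antigen, at 2648 ± 220 TPM, and Csf1r, the receptor for macrophage colony-stimulating factor, at 426 ± 61.8 TPM. The lowest member was Cebpa, a myeloid transcription factor, at 51.9 ± 27.2 TPM. Interferon-stimulated genes were also high, with 20 of 20 detected, 19 at 100 TPM or more, and a median of 592 and 624 TPM. Irf7, a transcription factor of the interferon response, reached 2211 ± 273 TPM, Ifit2 2023 ± 243 TPM, Isg15 1787 ± 137 TPM and the chemokine Cxcl10 1071 ± 238 TPM, while Mx2 was lowest at 83.6 ± 26.1 TPM. Against 10000 random lists of protein-coding genes of the same size, the medians of both lists lay at the 100th percentile in each library. The pool held undetected genes, and glycolysis, MHC class I and Toll-like receptor genes also lay there, so this position was not particular to the 2 lists. Against detected genes alone both lists stayed at the 100th percentile, as did glycolysis and MHC class I genes.

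Early and late inflammatory genes covered a wide range of levels after restimulation. Among 17 primary response genes, all detected, the median was 71.4 TPM in replicate 1 and 230 TPM in replicate 2. Tnf, the cytokine tumour necrosis factor (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), stood at 451 and 1198 TPM, the chemokine Ccl3 at 705 and 613 TPM, and Nfkbia, which encodes the NF-kB inhibitor IkB alpha, at 237 and 566 TPM. Among 16 secondary response genes 12 were detected, with medians of 41.2 and 43.0 TPM. Within this list Saa3 and Ccl5 were above 10000 TPM, and Acod1, the enzyme that makes itaconate, stood at 788 ± 267 TPM. By contrast Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) stood at 0.89 and 8.34 TPM, Il12b at 9.52 ± 1.53 TPM, Nos2, the inducible nitric oxide synthase, at 11.9 ± 6.51 TPM, and Csf3 at 0.12 and 0.08 TPM. The anti-inflammatory cytokine Il10 stood at 48.7 and 98.2 TPM. Mean log2(TPM + 1) was 6.84 over the primary genes and 5.79 over the secondary genes, a difference of 1.06 that did not pass a two-sided permutation test over genes (p = 0.378, 17 against 16 genes). With detected members alone the difference was -0.65 (permutation p = 0.548). Genes are not independent replicates, so this p describes the lists and not the cultures.

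Immediate-early genes, which encode mainly transcription factors and feedback regulators, were detected for 20 of 22 members. Their median was 69.5 TPM in replicate 1 and 163 TPM in replicate 2. By the mean of both libraries Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, was highest at 587 ± 283 TPM, followed by Junb at 301 ± 137 TPM and Atf3 at 269 ± 19.4 TPM, and Egr3 was lowest at 1.72 ± 1.03 TPM. The order differed by library, with Atf3 at 256 and 283 TPM and Junb at 205 and 398 TPM. In replicate 1 Fosb was lower than Egr3, at 0.92 against 0.99 TPM. Components of the Tlr4 pathway were all detected, 23 of 23, with medians of 30.3 and 28.0 TPM. The co-receptor Cd14 stood at 202 and 428 TPM, the adaptor Myd88 at 145 ± 0.764 TPM, and Tlr4 itself at 41.5 ± 9.81 TPM. Toll-like receptors had a median of 78.7 and 74.5 TPM, with 11 of 12 detected, Tlr1 highest at 172 ± 17.6 TPM and Tlr5 lowest at 0.275 ± 0.0354 TPM. Among negative regulators of Toll-like receptor signalling, 21 of 22 were detected, with medians of 55.6 and 81.5 TPM. Irak3, a kinase-dead inhibitor of the pathway, stood at 37.9 ± 0.912 TPM and Tnfaip3, which encodes the ubiquitin-editing enzyme A20, at 71.6 and 170 TPM. The 11 genes of the NF-kB and IkB families were all detected, with medians of 37.4 and 51.3 TPM.

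MHC class I presentation genes had medians of 552 and 556 TPM, led by B2m and by H2-K1 at 9235 ± 394 TPM, which shares sequence with other class I genes, so that its level is uncertain. MHC class II genes had medians of 92.1 and 151 TPM, led by Cd74, the invariant chain, at 430 and 750 TPM. Glycolysis genes had medians of 228 and 211 TPM, with Gapdh at 1878 ± 198 TPM, and cholesterol synthesis genes medians of 30.0 and 24.0 TPM, with Msmo1 at 98.0 ± 16.7 TPM. Heat shock genes had medians of 64.2 and 63.3 TPM, with the constitutive chaperone Hspa8 at 1814 ± 34.5 TPM. Alternative activation markers had medians of 2.76 and 3.61 TPM, with 7 of 12 detected. Il4ra, the receptor for interleukin-4, stood at 141 ± 34.0 TPM and the mannose receptor Mrc1 at 37.2 ± 6.00 TPM, whereas Retnla had 0 counts in both libraries, which allows up to 0.0715 and 0.0975 CPM. Cell cycle genes had medians of 6.46 and 5.08 TPM, with Pcna, the replication clamp, at 237 ± 8.55 TPM and Plk1 at 1.48 ± 0.0849 TPM.

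Markers of other marrow cells were low, with the exception of stromal genes. No listed T cell, NK cell, mast cell or erythroid marker reached 1 TPM in both libraries. Detected members numbered 1 of 6 for B cells, Cd79b at 5.87 ± 2.70 TPM, and 1 of 7 for dendritic cells, Ccr7 at 2.51 ± 0.141 TPM. For neutrophils 2 of 9 were detected, S100a8 and S100a9. All 7 stromal markers were detected, with medians of 28.0 and 33.9 TPM, and Col1a1, Col1a2 and Col3a1, which encode fibrillar collagens, stood at 229 ± 20.4, 173 ± 17.9 and 154 ± 11.2 TPM.

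Early-response genes were mostly higher in replicate 2. All 22 immediate-early genes had a higher scaled count in replicate 2, 15 of them at least 2-fold, with a median log2 ratio of 1.15 against -0.05 in random lists matched on expression. Among primary response genes 13 were higher and 4 lower in replicate 2, 11 of them at least 2-fold higher, with a median log2 ratio of 1.38. The ratio of Tnf was 1.45 (interval 1.43 to 1.48), of Il1b 1.91 (1.84 to 1.98), of Ptgs2, which encodes cyclooxygenase 2, 2.70 (2.60 to 2.81), of Cxcl2 2.57 (2.47 to 2.67) and of Fos 1.23 (1.19 to 1.27). The 4 lower genes were the chemokine genes Ccl2, Ccl3, Ccl4 and Ccl7, with Ccl3 at -0.19 (-0.24 to -0.15) and Ccl7 at -0.57 (-0.63 to -0.52). The medians of both lists exceeded those of all matched random lists (100th percentile of 10000). With 1 library on each side these ratios have no replicate check and no p was computed.

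**Figure D1:**
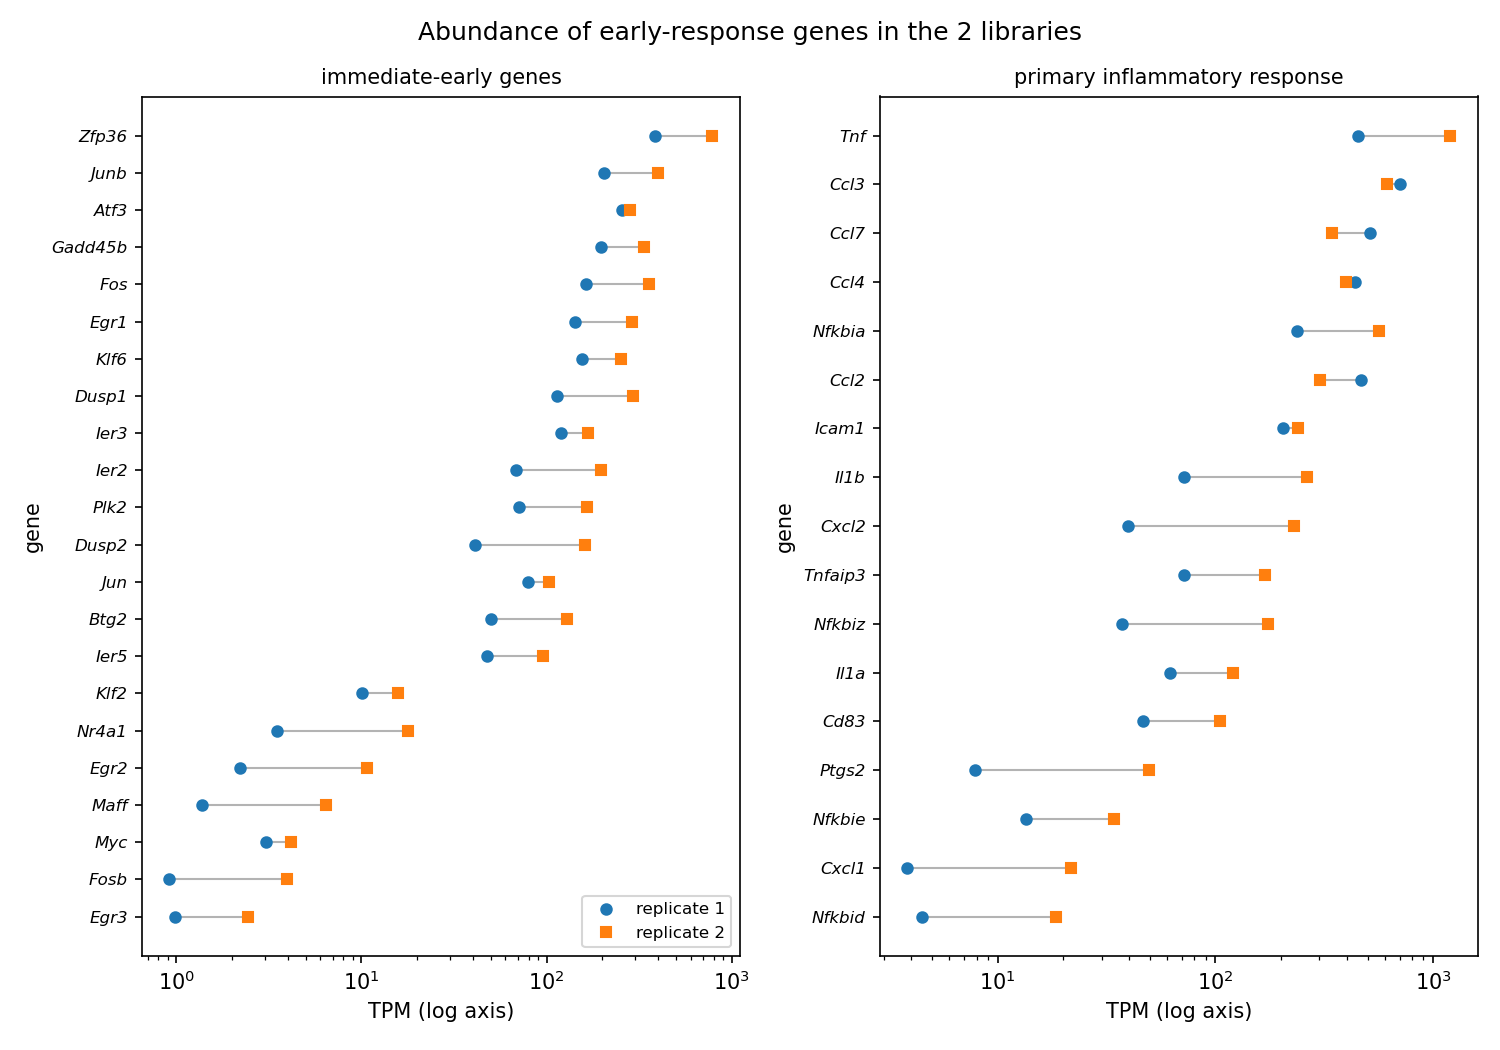
TPM (log axis) of each immediate-early gene and each primary inflammatory response gene, with circles for replicate 1 and squares for replicate 2. All 22 immediate-early genes lie higher in replicate 2, and Ccl2, Ccl3, Ccl4 and Ccl7 lie lower.

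Other lists differed in both directions. All 8 MHC class II genes were higher in replicate 2, with a median log2 ratio of 0.84 (percentile 100), including H2-Aa at 0.95 (0.89 to 1.01) and the class II transactivator Ciita, at 2.26 and 5.53 TPM. Secondary response genes, with 13 of 16 counted, had a median of 0.28 (percentile 99.9). Il6 was highest, at 0.89 and 8.34 TPM, a log2 ratio of 3.44 (2.81 to 4.20) on 21 and 170 counts. Il10 stood at 1.05 (0.95 to 1.15), and Il1rn, the interleukin-1 receptor antagonist, was lowest at -1.06 (-1.10 to -1.02). The NF-kB and IkB list had a median of 0.28, and 0.26 without the 4 members shared with the early lists. Negative regulators had a median of 0.12 (percentile 99.7), and 0.00 without the 4 members they share with the early lists. Both removals were added after the data were seen, and the shortened lists were not set against matched lists. All removed members had ratios above the median of their list, so their removal could not raise it. Interferon-stimulated genes had a median of 0.05 (percentile 94.7), with 11 higher and 9 lower. Macrophage identity genes had a median of -0.20 (percentile 2.36), with Cd14 at 1.07 and Cebpa at -1.06. Cell cycle genes had a median of -0.38 (percentile 0), 19 of 20 lower in replicate 2, such as Cdk1 at -0.60 (-0.79 to -0.41).

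Marker and RNA-class values moved beside these groups. The 4 neutrophil markers with a mean of at least 20 counts were all lower in replicate 2, with a median of -3.56, among them S100a9 at 40.1 and 5.28 TPM and Ngp, a granule protein, at 10.2 and 0.40 TPM. Only S100a9, with 277 and 26 counts, had at least 20 counts in both libraries. The others passed through replicate 1, as Ngp did with 272 and 8 counts, so the median rests on few counts in replicate 2. All 7 stromal markers were slightly higher in replicate 2, with a median of 0.27 (percentile 99.75), outside the central 95% of matched lists. The nuclear rRNA gene CT010467.1 took 1.37% of counts in replicate 1 (1.37 to 1.38%) and 4.25% in replicate 2 (4.25 to 4.26%). Medians of the remaining lists were -0.02 for Tlr4 pathway components, -0.15 for Toll-like receptors, 0.14 for alternative activation markers, -0.08 for glycolysis, -0.02 for cholesterol synthesis, 0.00 for MHC class I, 0.02 for heat shock genes, -0.06 for mitochondrially encoded proteins and 0.17 for sex-linked genes, all within the central 95% of matched lists.

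**Figure D2:**
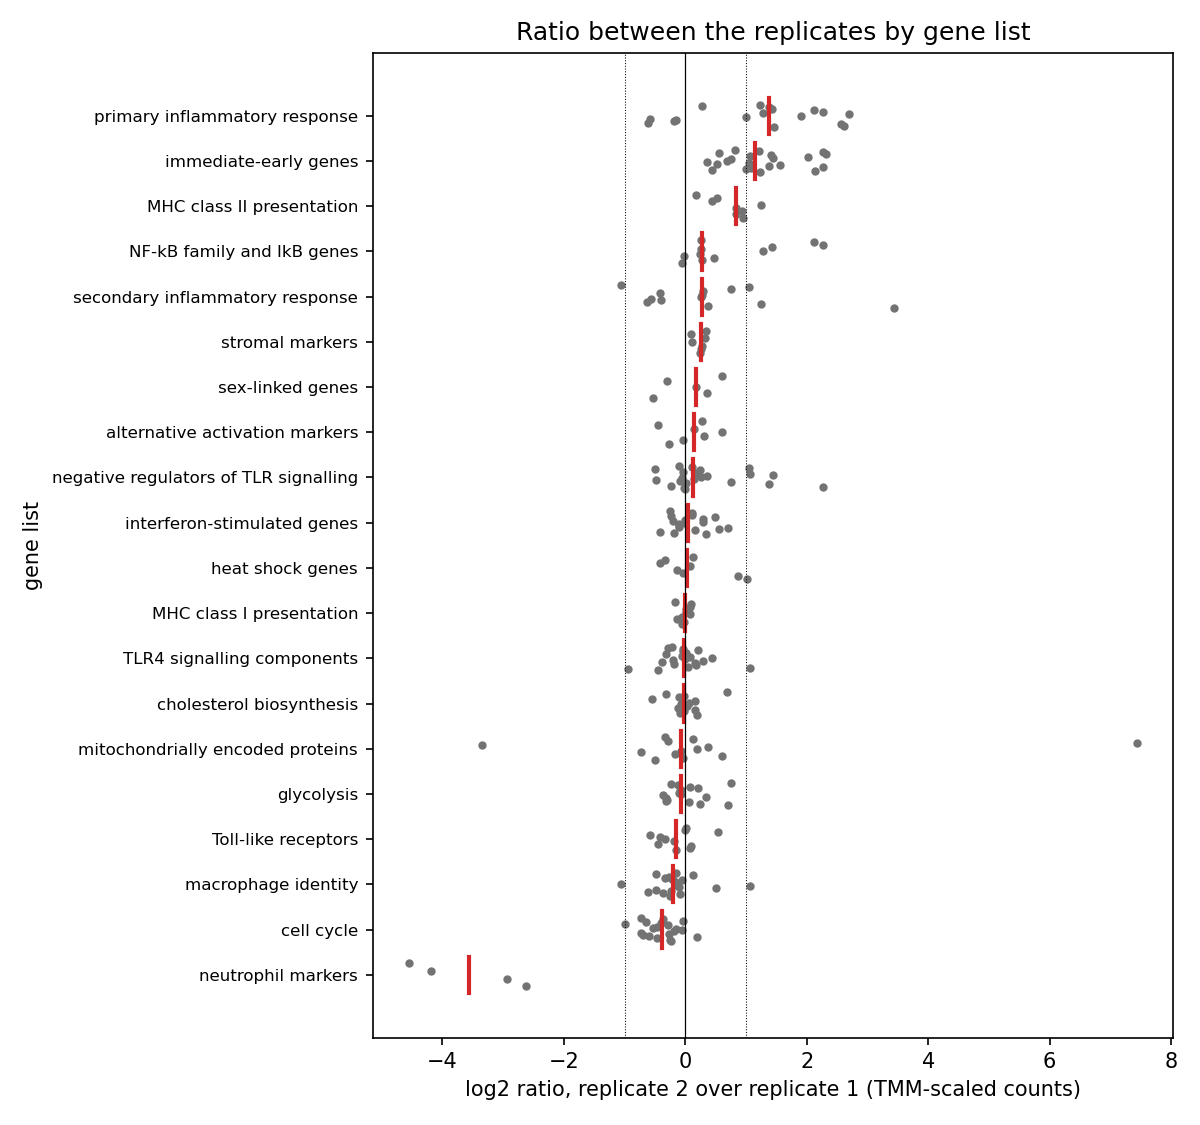
Log2 ratio of scaled counts, replicate 2 over replicate 1, for each counted member of each gene list (grey points), with the list median as a red bar and dotted lines at 2-fold. Primary response and immediate-early genes have the highest medians, 1.38 and 1.15, and neutrophil markers the lowest, -3.56.

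Across all genes the libraries were close. Over 12332 genes at 1 TPM or more in either library, Pearson's r was 0.977 and Spearman's rho 0.977 on log2(TPM + 1), a correlation across genes, which are not independent replicates. The biological coefficient of variation was 16.6% over 13429 genes. As a check for a library deposited more than once, the counts were compared with sampling noise, and chi-square was 87.0 per degree of freedom over 15263 genes. Among 12471 genes with at least 20 counts in both, 244 were at least 2-fold higher and 65 at least 2-fold lower in replicate 2, and 33 of the higher and 4 of the lower belonged to a gene list. These numbers depended on the count filter, with 104 higher and 32 lower at 100 or more counts in both, and 1455 and 609 without a filter. Tnfsf9, a costimulatory ligand (chromosome 17, 57105325 to 57107757), had the highest ratio among these genes, at 2.84 and 61.4 TPM, a log2 ratio of 4.47 (4.15 to 4.82), and Susd2 reached 2.96. Cd36, a scavenger receptor for lipids (chromosome 5, 17781690 to 17888801), was among the lowest at 145 and 41.1 TPM, a log2 ratio of -1.76 (-1.82 to -1.69). The pseudogene Gm12671 had 1060 counts in replicate 1 and 0 in replicate 2, at least 258-fold lower against a floor of 3 counts, and almost none in the FASTQ-derived table, so its value is uncertain.

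The deposited files hold 2 quantifications of each library, and they gave nearly the same order of genes. Over 10820 protein-coding genes at 1 TPM or more in both tables, Spearman's rho across genes was 0.994, and 82 genes (0.758%) differed at least 2-fold after centring on the median. Mitochondrial genes were among the farthest apart. Mt-Atp6, a subunit of ATP synthase, stood at 38.6 TPM in the alignment-derived table and 3237 TPM in the FASTQ-derived table, mt-Co3, a subunit of cytochrome oxidase, at 26.9 and 1061 TPM, and mt-Atp8 at 23493 and 5054 TPM. Klf10 stood at 16.1 and 3041 TPM, and Rps12 and its copy Rps12-ps3 exchanged places, at 558 and 13.7 TPM for Rps12 and 12.3 and 549 TPM for the copy. Pseudogenes on chromosome 1 between 24611535 and 24616197 (mm10) share their sequence with mitochondrial genes. Gm10925, Gm28437 and Gm28661 had 100% of their 31-mers in mitochondrial transcripts and carried 49096, 61420 and 77672 counts in the alignment-derived table of replicate 1. Levels of these pseudogenes, of mt-Atp6, of mt-Co2, whose ratio between the replicates was -3.35, and of mt-Co3, whose ratio was 7.43, are therefore uncertain. The differences for mt-Atp8, Klf10 and Rps12 were not traced to these pseudogenes, and the levels of those genes are uncertain too.

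**Figure D3:**
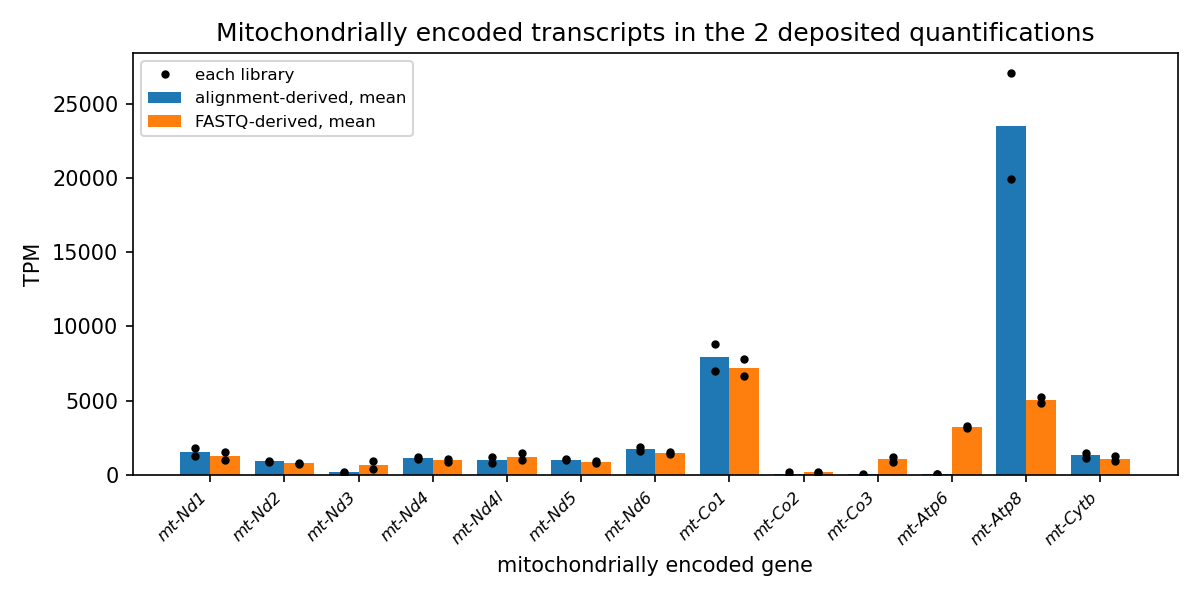
TPM of the 13 mitochondrially encoded protein genes in the alignment-derived and FASTQ-derived quantifications, as bars for the mean of both libraries and points for each library. Mt-Atp8 is higher in the alignment-derived table (23493 against 5054 TPM) and mt-Atp6 in the FASTQ-derived table (38.6 against 3237 TPM).

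Transcripts annotated as retained intron or processed transcript were a small part of most genes. Over 6918 protein-coding genes at 10 TPM or more, their median share of the gene's TPM was 1.10%, and 1313 genes exceeded 10%. Immediate-early genes, with 17 of 22 counted, had a median of 0% (percentile 0.71 of matched lists). Primary response genes had 1.95% (percentile 89.8), with 0.989% in replicate 1 and 2.26% in replicate 2. MHC class I genes had a median of 12.7% (percentile 99.8) and Tlr4 pathway components 7.16% (percentile 99.1). The share can exceed 0 only where such a transcript is annotated, and the random lists were matched on expression alone. These percentiles can therefore reflect annotation, and no conclusion on splicing was drawn from them. Cd14 carried a retained-intron transcript, Cd14-202, at 12.4% and 18.3% of its TPM. Several inflammatory genes divided their TPM among coding transcripts. Dusp1, a phosphatase that limits MAP kinase signalling, had 54.1 ± 6.94% in one transcript and 41.2 ± 5.92% in another, with 49.8% and 44.7% in replicate 1 and 36.1% and 56.3% in replicate 2 of the FASTQ-derived table, so that the order turned in replicate 2 alone. Irak3 had 65.0% and 34.0% in its main transcripts in replicate 1 and 49.0% and 50.4% in replicate 2, with means of 74.8% and 22.7% in the FASTQ-derived table. The leading transcript held 61.4 ± 1.68% of Tnfaip3 and 82.8 ± 3.09% of Zfp36 (SD, n = 2). Il6 also divided its TPM, but on 21 counts in replicate 1.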

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

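No test was added here after the result was seen. PhiX174, a bacteriophage genome used as a control on sequencing runs, stood above the floor of 3 counts in the gene table and the FASTQ-derived table of both replicates, a signal outside the measured genes. It held 22091 counts in the alignment-derived gene table and 25083 in the FASTQ-derived transcript table of replicate 1, and 20542 and 23065 in those of replicate 2. The synthetic spike-in ERCC-00099 held 5 counts in the FASTQ-derived table of each replicate and 0 in the alignment-derived gene table. The floor of 3 counts is what a count of 0 allows and not a detection limit, so 5 counts do not show that the spike-in was present. With 2 libraries in 1 group, no library was tested for standing apart from the rest and no effects could be set against each other.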

How the results depend on the processing

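The filter that kept immediate-early genes at a mean TPM of at least 10 and the removal of shared members from a list were added after the results were seen. Across 40 results and 141 alternatives, the direction of the median ratio held for 19 of 20 lists under other scaling factors and the FASTQ-derived table, and it changed for heat shock genes, whose median was near 0. The median log2 ratio of immediate-early genes was between 1.12 and 1.15 under other scaling and the FASTQ-derived table, and 1.07 for the 17 members at a mean TPM of at least 10. For primary genes it was between 1.37 and 1.38, and the same filter removed none of them. With detected members alone, the difference between primary and secondary genes turned to -0.65 because 4 secondary genes left the list, and its permutation p ran from 0.191 to 0.631 over the alternatives. Genes at least 2-fold higher and lower in replicate 2 numbered 104 and 32 at 100 or more counts and 1455 and 609 without a count filter, which admits genes of few counts. Genes beyond 2-fold between quantifications made up 9.18% without a filter and 0.38% at 10 TPM or more. The SD of the log2 ratio between replicates was 0.458, 0.72 with a pseudocount of 0.1 and 0.232 without a filter. The leading 10 genes of each measure took 11.4% of expected counts and 13.4% of TPM in the FASTQ-derived table, where the list medians of macrophage identity, interferon-stimulated and secondary genes were 1086, 527 and 36.3 TPM and that of mitochondrially encoded proteins had a log2 ratio of -0.22. The cause of the lower TPM was not tested, though Mir6236 took 9.97% and 14.8% of TPM in the FASTQ-derived table and 0 in the alignment-derived one. It held 0.144% and 0.185% of counts in the FASTQ-derived table. TPM add up to a fixed total, so this share by itself lowers the TPM of other genes there. It does not bear on the 11.4% of expected counts or on the ratio of -0.22, which rest on counts. Against detected genes alone, secondary genes lay at the 97.7th percentile. The share of non-coding transcripts in primary genes ran from 0.989% to 2.26% with either replicate left out. Negative regulators without the shared members had a median of 0.0007. No paired analysis was possible because the series holds 1 group, and no library could be left out of a ratio between the libraries. Depth limits markers under a mean of 20 counts, which carried no ratio. Markers above that mean through 1 library alone did carry a ratio, such as Ngp with 272 and 8 counts.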

Other observations

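The tests of scaling and of other cell types for the early-response genes were chosen after the result was seen. Transcripts of both sex chromosomes were present. Xist, the RNA that silences an X chromosome in females, stood at 50.9 TPM in replicate 1 and 34.0 TPM in replicate 2, while the Y-linked genes Ddx3y and Eif2s3y stood at 1.73 and 2.27 TPM and at 1.71 and 2.13 TPM. The Y-linked signal was weak, with 210 and 196 counts for Ddx3y and 73 and 60 for Eif2s3y, against 19938 and 10100 for Xist. The other listed Y-linked genes, Kdm5d and Uty, did not reach 1 TPM in both libraries. Sex was not collected per the labels. Among markers of other cells, the erythroid marker Epor, the erythropoietin receptor, had 91 and 13 counts and the B cell marker Cd79b 216 and 80 counts in replicates 1 and 2.

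Other fibroblast genes were present beside the listed stromal collagens. A list of 20 fibroblast genes, 5 of them further collagen genes, written before its values were seen and sharing no member with the other lists, was at a TPM of at least 1 in both libraries for 100% of its members, against 48.7% of protein-coding genes. Sparc stood at 184 ± 14.6 TPM, Bgn at 113 ± 13.8 TPM, Serpinh1 at 89.1 ± 8.78 TPM, Postn at 85.9 ± 6.07 TPM and Lox at 69.6 ± 8.67 TPM (SD, n = 2), and 19 of 20 were higher in replicate 2, with a median log2 ratio of 0.26. Fibroblast-like cells in the cultures are a candidate source of the collagen transcripts. How many of these genes macrophages themselves express was not measured, since no sorted library was analysed here, and no biological explanation was tested.

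Immediate-early and primary response genes, 39 in all, had a median log2 ratio of 1.23 between the libraries, with 35 higher in replicate 2. After the trend with GC content and transcript length was removed, which explained 0.661% of the variance, the median was 1.227, which argues against that trend as the whole cause. A ratio at least as high as the median was held by 1.257% of protein-coding genes. One scaling factor per library moves all genes alike, so it cannot place these genes above the others. The share itself does not change with that factor and restates the excess over matched lists, so it is no independent test. Neutrophil markers were lower, and all 7 stromal markers were higher with a median ratio of 0.267, too small a difference to account for that of the early genes, and types with fewer than 3 counted markers, dendritic cells among them, were not tested. Among what stays open are a different timing or strength of the response, handling of the cultures, and RNA quality or library preparation, which were not tested although the share of the rRNA gene CT010467.1 rose from 1.37% to 4.25% of counts in replicate 2, and the design names no biological difference between replicates that could be tested.

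The low values of mt-Co3 and mt-Atp6 in the alignment-derived gene table may come from reads assigned to nuclear copies. Summed over mitochondrially encoded protein genes and 7 pseudogenes on chromosome 1 sharing at least 97.2% of their 31-mers with them, counts of the FASTQ-derived table were 1.079 times those of the alignment-derived table in replicate 1, the library farther from 1. The same ratio over all genes was 1.10. For mt-Co2, mt-Co3 and mt-Atp6 pooled it was 31.5 in replicate 1 and 51.2 in replicate 2, carried by mt-Co3 and mt-Atp6. The pooled genes held 2411 and 75924 counts in the alignment-derived and FASTQ-derived tables of replicate 1, against a sum of 666462 in the former. From the alignment-derived to the FASTQ-derived table, the 7 pseudogenes together fell from 217481 to 134732 counts in replicate 1. In replicate 2 they fell from 194926 to 139184. The pooled genes rose while the copies fell, which goes with reads shared between them. The reads themselves were not traced, so these totals do not settle whether reads went to copies. In the same order of tables, Gm10925, closest to mt-Atp6, held 49096 and 3434 counts in replicate 1 and 49904 and 15990 in replicate 2. Gm28437, closest to mt-Co3, held 61420 and 41418, and 70671 and 60610. The gene mt-Co2 was low in both tables, at 165 and 219 TPM in replicate 1 and 16.1 and 129 TPM in replicate 2, with its copy Gm28661 at 77672 and 79418 counts in replicate 1, so its low level and whether the copies are themselves transcribed stay open, and no biological explanation was tested.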
